A study of Rattus norvegicus with 6 samples.

How the data were processed

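Total RNA was extracted with Trizol from tissue labelled testicle, depleted of rRNA, treated with RNase R, fragmented and made into libraries with a NEBNext Ultra kit, per the labels' protocols. Reads were paired-end on an Illumina HiSeq instrument. The submitters' processing notes name the build rn6 and the tools Trimmomatic 0.36, FastQC, BWA, TopHat, HISAT2, HTSeq and DESeq, without their roles or order. The circRNA caller and any strand setting are not given in the sources used here, so reads from a gene and an antisense or overlapping partner cannot be told apart.

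Both tables cover the whole series. The deposited counts are whole numbers of reads per ncRNA transcript and of back-splice reads per circRNA, with no normalization, per the file headers and the values. The ncRNA table also holds a normalized signal per group, which the authors computed as the mean of counts divided by size factors (found from the values, which each group's counts rebuild exactly). It holds the authors' fold change, a ratio of these means, and the authors' p-value and q-value, by a test not given in the sources used here. The circRNA table holds RPM values, which the authors computed from the counts and library totals larger than those of the table, as the values themselves show. The lowest non-zero circRNA count was 2. In 3 circRNA rows the host symbol had turned into a date, and these hosts matched no list.

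Samples were assigned to groups by the genotype label, 3 libraries each. Columns were matched to samples by the sample titles. The labels do not say whether each library came from its own animal, so p-values measure the spread between these libraries. Pairs of libraries within a group differed by more than sampling noise, with chi-square values per degree of freedom of 10.8 to 252 for ncRNAs and 6.02 to 9.83 for circRNAs, and each was counted as a replicate. The libraries are named by their labels throughout, because no row measured Hmox1.

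Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with robust estimation and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). The count filter was filterByExpr with a minimum count of 10 and a minimum total of 15 for ncRNAs, and of 5 and 10 for circRNAs. Library sizes were the totals of each table. CPM values are after TMM, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts per library, and where a group had 1 to 3 counts in all, a ratio of counts with an exact 95% interval is given. The floor equals 0.531 to 0.916 CPM after TMM in the ncRNA table and 426 to 860 in the circRNA table. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 (correlation 0.01, on log2 CPM with a prior count of 2). Values per library were compared by exact permutation.

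The tests, the 13 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per table, the 10 largest rises and 10 largest falls in log2 fold change among those with an adjusted p under 0.05, mean abundance above the median of tested features and no overlap between groups, filled to 5 per direction by the smallest unadjusted p. It added the 5 most abundant features, up to 4 members of each list by the smallest p, and a set of genes always named (Hmox1, Tox, Jun, Mir221, Mir222, Malat1, Neat1, H19, Meg3, Cdr1as). Of the circRNAs that the rule took, 1 is not reported here. The lists for hepatocyte, kidney tubule, heart and skeletal muscle, and neuron, and those of sex-dependent rat liver genes, were written after the tables had been seen, and Cps1 and Alb, like the miRNA precursors, Cyp2c11, Cyp2c13, Ust5r, Ddx3 and Zbtb16, were chosen for mention after their values were seen. Of the 6695 ncRNA rows, 1279 were matched to the GRCr8 gene table by accession, 1368 by symbol and 33 by synonym, and 4015 had no match. That table was used for names and neighbours only, and coordinates are those of the deposited circRNA table. A planned test of ncRNAs within 10 kb of listed genes was not run, because no annotation of rn6 was given.

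On simulated counts with the real means, library sizes and spread, in 20 draws with 200 of 1787 ncRNAs changed, the ncRNA test recovered a mean of 62.8% (46.8% to 70.3%) of those changed by a log2 of 3 and 4.80% (0.943% to 9.26%) of those changed by 1, with a mean of 2.80 false calls and at most 8. With 30 of 167 circRNAs changed, the circRNA test recovered a mean of 21% (0% to 45.5%) and 0.774% (0% to 8.33%), with at most 3 false calls. With 0.1 times that dispersion it recovered 89.7% and 13.9%. The circRNA comparison could therefore miss even large changes.

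The alternatives were other scaling factors, library totals alone, DESeq2 1.42.0, limma's voom with sample quality weights, non-robust dispersion, no filter, a stricter filter (at least 30 or 20 counts in 3 libraries), an unadjusted threshold with an absolute log2 fold change of at least 1, a replicate block, each library left out in turn, circRNA library sizes from the ncRNA table and circRNA counts summed per host. Set tests were also run with an estimated correlation and with fry. Alternatives added after seeing the data were circRNA library sizes from the authors' RPM, the ncRNA test without Rn7sl1 and the row named Rmrp, and both tests without replicate 1 of either group.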

Results

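Non-coding and circular RNAs were sequenced from 6 libraries that the labels describe as testicle of male Sprague Dawley rats. All animals had a 720 degree torsion of the left testicle for 2 h, followed by reperfusion for 3 days. Of these libraries, 3 were labelled HO-1 knockout and 3 wild type, where HO-1 is heme oxygenase 1, the stress-inducible enzyme that degrades heme, encoded by Hmox1. No untorted or sham library was analysed here, so each comparison below is between genotype labels after injury. RNA depleted of rRNA had been treated with RNase R, which digests linear RNA and leaves circular RNA. Counts of linear ncRNAs below are therefore of what remained after digestion. How evenly it acted across the libraries is not known from these data. The ncRNA table held 6695 transcripts of 6213 genes, and the circRNA table held 1284 circRNAs from 939 host genes.

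Total ncRNA counts were 5306370, 4825426 and 4886014 in the knockout-labelled libraries and 4171371, 4437197 and 5014095 in the wild-type-labelled ones, in order of replicate number. A single transcript, Rn7sl1, the RNA of the signal recognition particle, took 75.16%, 72.08% and 70.87% of these counts in the knockout-labelled libraries and 66.05%, 62.44% and 68.84% in the others. Knockout-labelled replicate 1 had counts for 4588 ncRNAs, against 3188 to 3557 in the other 5 libraries. It held 523 transcripts with at least 10 counts that had none elsewhere. The row named Rmrp took 17.65% of the counts of wild-type-labelled replicate 1 and 6.56% to 8.46% of the others. Circular RNA was counted far more thinly, with 4988, 4549 and 4928 back-splice counts in the knockout-labelled libraries and 3966, 3954 and 7721 in the wild-type-labelled ones. Of the circRNAs, 843 were seen in 1 library and 47 in all 6.

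The labels name a knockout, so the targeted gene would check them, but no row of either table measured Hmox1. The genotype of the libraries was therefore taken from the labels alone. The study's title names c-Jun, miR-221, miR-222 and TOX, and the question the labels pose is how ncRNAs and circRNAs differ between the genotypes after torsion. The precursor Mir221 had 0, 0 and 1 counts in the knockout-labelled libraries and 4, 1 and 8 in the wild-type-labelled ones. Mir222 had 0 counts in each knockout-labelled library and 4, 0 and 4 in the others. Both were below the count filter and were not tested. A circRNA from Tox, at chromosome 5, 19943304 to 19943585 of rn6, had 8 counts in knockout-labelled replicate 1 and none in the other 5 libraries. Jun, Malat1, Neat1 and Cdr1as had no row in the tables used here.

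Of 1787 ncRNAs tested, 71 changed between the labelled groups, 34 higher and 37 lower in the knockout-labelled libraries (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The transcript listed as LOC100911498, whose accession NR_132635.1 belongs to Xist, the lncRNA that silences an X chromosome in female cells, was at 5406 ± 895 CPM (counts scaled by library size after TMM) in the knockout-labelled libraries and 16.5 ± 11.002 in the wild-type-labelled ones (mean ± SD, n = 3 each, as for all CPM values). Its log2 fold change was 8.34 with a standard error of 0.54 (adjusted p = 6.05e-07), and the Sex label of all 6 libraries is male. Xist and the genotype label divided the libraries in the same way. None of the 71 changes can therefore be assigned to HO-1 loss from these data. Among the 37 that fell in this test, the change was largest in absolute CPM for ENSRNOG00000000978.7, a processed transcript without a name in the files, at 18.5 ± 12.0 against 10538 ± 2705 CPM, with a log2 fold change of -9.15 and a standard error of 0.62 (adjusted p = 1.53e-06). All 71 changed ncRNAs had no overlap between the groups, against 19.81% of the tested ncRNAs, where chance gives 10%. The test itself selects features that differ beyond the spread within groups, so this is no separate support for the calls.

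**Figure D1:**
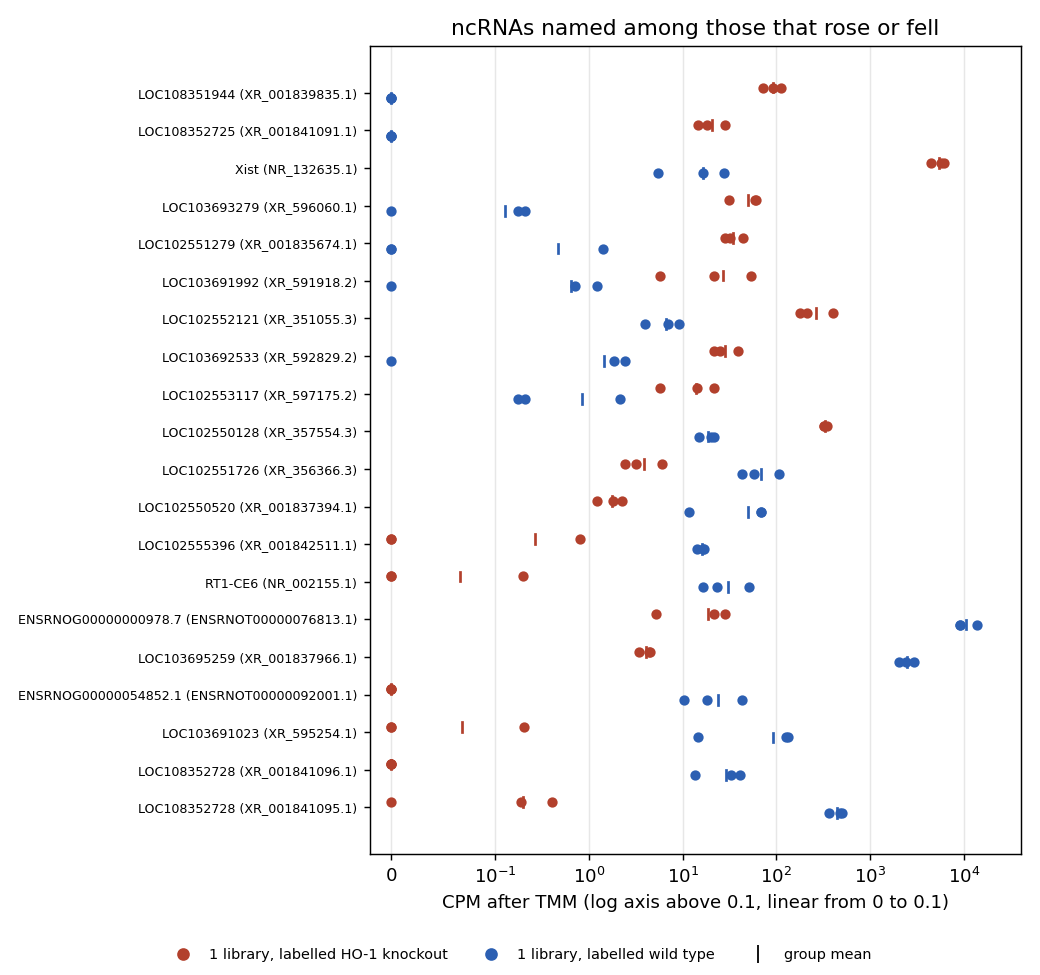
CPM after TMM of the 20 named ncRNAs that rose or fell, on a log axis that is linear from 0 to 0.1, with a point per library and a bar at each group's mean. These were named from changed ncRNAs without overlap between the groups, and the group means of Xist were 5406 and 16.5 CPM.

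Most of the other named ncRNAs that rose are uncharacterised loci. LOC102550128 was at 328 ± 13.5 against 18.8 ± 3.42 CPM, a log2 fold change of 4.13 with a standard error of 0.30 (adjusted p = 1.53e-06). LOC102552121 was at 264 ± 123 against 6.67 ± 2.62 CPM. LOC108351944 had 358, 542 and 490 counts in the knockout-labelled libraries and 0 in each of the others, so that it was at least 133-fold higher against a floor of 3 counts per library. LOC108352725 likewise had no wild-type-labelled counts and was at least 29.5-fold higher. LOC103693279 had 761 counts against 2, a ratio of 344 with a counting interval of 95.02 to 2849. LOC102551279, LOC103691992, LOC103692533 and LOC102553117 rose as well, with log2 fold changes of 5.94, 5.42, 4.36 and 4.16. These rested on few wild-type-labelled counts. Without wild-type-labelled replicate 2, which held all 8 of those of LOC102551279, they were 10.3 for LOC102551279, 3.65 for LOC103692533 and 3.56 for LOC102553117. Without replicate 1 of that group they were 6.11 for LOC103691992, 4.96 for LOC103692533 and 6.03 for LOC102553117, and for LOC103691992 the value was 4.82 without wild-type-labelled replicate 3 and 4.40 without knockout-labelled replicate 3. The 10.3 for LOC102551279 is a model fit with no wild-type-labelled counts left, so its size is not a measured fold. LOC102553117 was at 13.9 ± 8.03 against 0.84 ± 1.12 CPM (adjusted p = 0.0285).

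Among the ncRNAs that fell, LOC103695259 was at 4.08 ± 0.604 against 2459 ± 443 CPM, a log2 fold change of -9.23 with a standard error of 0.34 (adjusted p = 1.52e-09). A transcript of LOC108352728 had 3 counts in the knockout-labelled libraries together and 1197, 2696 and 2398 in the others, a ratio of 2317 with a counting interval of 792 to 11237. A second transcript of that locus had 0 counts in each knockout-labelled library and was at least 48.6-fold lower there. ENSRNOG00000054852.1, a lincRNA, was also without counts in them and at least 40.5-fold lower. RT1-CE6, a transcript of the class I histocompatibility region, had 1 count against 77, 94 and 247, a ratio of 462 with a counting interval of 82.4 to 18283. It lies between RT1-CE7 and RT1-CE3 in GRCr8 and is uncertain, because near-identical copies in that region can share reads. LOC103691023 had 1 count against 436, 706 and 70, a ratio of 1339 with a counting interval of 240 to 52930. LOC102551726, LOC102550520 and LOC102555396 fell with log2 fold changes of -4.14, -4.79 and -5.78. Without knockout-labelled replicate 1, which held all 4 knockout-labelled counts of LOC102555396 and the 1 of RT1-CE6, the log2 fold changes of these went from -5.78 to -9.26 and from -8.37 to -10.2. Without replicate 2 of that group those of LOC103691023 and the first LOC108352728 transcript went from -9.95 to -11.8 and from -10.96 to -11.85. Without wild-type-labelled replicate 3 those of RT1-CE6 and ENSRNOG00000054852.1 were -7.79 and -9.11. The values -9.26, -10.2, -11.8 and -9.11 come from fits with no knockout-labelled counts left, so their size is not a measured fold.

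These calls came from 3 libraries a group, and knockout-labelled replicate 1 stood apart in the number of ncRNAs it held. Without it 69 ncRNAs were called, 58 of them among the 71, and without replicate 3 of that group the number that rose went from 34 to 21. The calls for LOC102553117, LOC103691992, LOC103692533 and LOC103691023 ended under limma's voom with quality weights. That for LOC102553117 also ended without knockout-labelled replicate 1 or 3 and without wild-type-labelled replicate 2 or 3, that for LOC103691992 without knockout-labelled replicate 3, and that for LOC103692533 with replicate 1 of both groups left out. In the authors' deposited table, 60 ncRNAs had a q under 0.05, of which 58 were among the 71 and all 58 had the same direction.

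The 5 most abundant ncRNAs did not pass the test. Rn7sl1 was at 720081 ± 69690 against 681899 ± 177386 CPM (adjusted p = 0.958), a difference that was smaller than the spread between libraries and changed sign without knockout-labelled replicate 1 or wild-type-labelled replicate 2. Before TMM its share of counts was 70.87% to 75.16% in the knockout-labelled libraries and 62.44% to 68.84% in the others. The groups overlapped only after TMM. The row named Rmrp, the RNA of RNase MRP, carries an accession that the GRCr8 table assigns to Rpph1, the RNA of RNase P, so its identity is uncertain. It was at 68280 ± 9184 against 123970 ± 88481 CPM (adjusted p = 0.357), with the highest value in wild-type-labelled replicate 1, without which the log2 fold change went from -0.86 to -0.0965. LOC680406 was at 39134 ± 4438 against 65946 ± 5901 CPM, just short of the threshold with an adjusted p of 0.0588. It passed under some alternatives: RLE factors, voom, no filter, the replicate block, Rn7sl1 and Rmrp left out, and wild-type-labelled replicate 1 or 2 left out. LOC103693047 was at 29809 ± 2757 against 42761 ± 10758 CPM (adjusted p = 0.36) and passed without wild-type-labelled replicate 1. A non-coding transcript of Itih2, which encodes an inter-alpha-trypsin inhibitor heavy chain secreted by hepatocytes, was at 16314 ± 1102 against 18043 ± 616 CPM (adjusted p = 0.888).

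Among 8 tested well characterised lncRNAs, 1 rose (Xist) and 7 did not pass the test, and the count adjusted over the list alone was also 1. Gas5, a snoRNA host transcript, was at 413 ± 64.2 against 292 ± 97.6 CPM (adjusted p = 0.569). Jpx, a lncRNA of the X inactivation centre, was at 13.2 ± 1.28 against 7.58 ± 4.78 CPM (adjusted p = 0.733), and Oip5-as1 at 1272 ± 108 against 1058 ± 303 CPM (adjusted p = 0.816). H19, an imprinted lncRNA, had 239 counts against 238 and an adjusted p of 0.911, and its log2 fold change of -0.339 was 0.466 without wild-type-labelled replicate 1. Meg3 had 14, 7 and 2 counts against 19, 0 and 0 and was not tested. The list as a whole did not pass camera (upward, adjusted p = 0.262, and adjusted p = 0.795 with an estimated correlation). None of 3 tested structural small ncRNAs passed over all ncRNAs or adjusted over the list alone, and Terc, the telomerase RNA, was at 71.4 ± 5.56 against 129 ± 85.9 CPM (adjusted p = 0.43), with a log2 fold change of -0.853 that was -0.159 without wild-type-labelled replicate 1. Of the list of c-Jun, TOX and cell death, a non-coding transcript of Mlkl was the tested member, at 9.31 ± 2.21 against 5.31 ± 5.002 CPM (adjusted p = 0.816). Its log2 fold change of 0.793 was 1.79 without wild-type-labelled replicate 3. For the meiosis list, 1 of 5 non-coding transcripts of Fancm was tested, at 1.57 ± 1.37 against 2.70 ± 0.576 CPM (adjusted p = 0.925).

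By the classes the table gives, 27 of the ncRNAs that rose and 29 of those that fell were of the class ncRNA, with 1206 tested. The lincRNAs had 4 rises and 3 falls among 101 tested, and processed transcripts 3 and 2 among 51. The class misc_RNA had 3 falls and no rise among 370. No antisense RNA of 12 tested, no precursor RNA of 35 and no retained intron of 7 passed. None of the classes moved as a set by camera, where the lowest adjusted p was 0.262, for antisense RNAs, with an adjusted p of 0.795 under an estimated correlation.

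Of 167 circRNAs tested, 2 rose and none fell in the knockout-labelled libraries by the same edgeR test, and 5 had an unadjusted p under 0.05. Both came from genes of the cytochrome P450 2C family, which in rat encodes liver enzymes of steroid and drug metabolism. Both host genes are also on the list of female-predominant rat liver genes, which was written after the tables had been seen. The circRNA from Cyp2c7 at chromosome 1, 148084420 to 148107916 of rn6, was at 84786 ± 1836 against 42920 ± 2811 CPM of circRNA counts, a log2 fold change of 0.98 with a standard error of 0.13 (adjusted p = 0.00523). The circRNA from Cyp2c12 at chromosome 1, 258731833 to 258755813, had 46, 39 and 49 counts in the knockout-labelled libraries and 0 in each of the others (adjusted p = 0.0485). It was at least 13.2-fold higher against a floor of 3 counts per library. Another tested Cyp2c12 circRNA, at 258754371 to 258754547, did not pass. It had 29, 25 and 0 counts in the knockout-labelled libraries and 0, 0 and 11 in the others. The 2 circRNAs that rose are uncertain as to gene, since reads at junctions of near-identical Cyp2c genes can be shared. DESeq2 called 0 circRNAs, with 9 at an unadjusted p under 0.05, and edgeR called 0 with library sizes taken from the ncRNA table and without knockout-labelled replicate 2 or replicate 3. Without knockout-labelled replicate 1 the call for Cyp2c7 ended, and with replicate 1 of both groups left out that for Cyp2c12 ended.

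**Figure D2:**
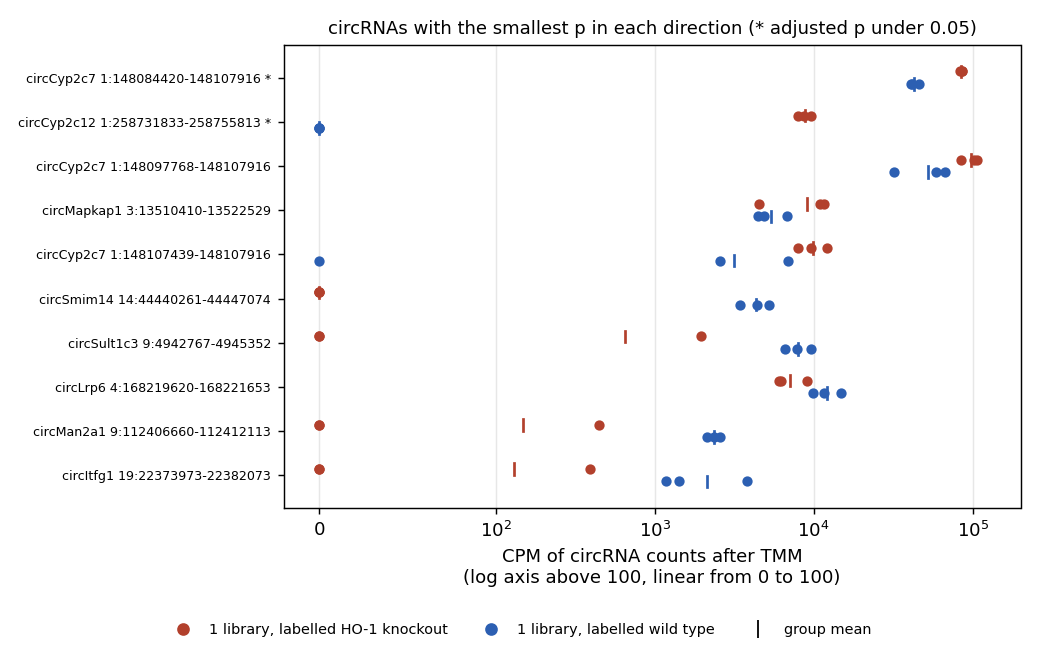
CPM of circRNA counts after TMM, on a log axis that is linear from 0 to 100, with a point per library, a bar at each group's mean and rn6 coordinates beside each host gene. The marked circRNAs of Cyp2c7 and Cyp2c12 passed the test, and the marked circRNA of Cyp2c12 had no counts in the 3 libraries labelled wild type.

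Other circRNAs named for the smallest p in each direction did not pass. A second Cyp2c7 circRNA, at 148097768 to 148107916, was the most abundant of all, at 97953 ± 11562 against 52657 ± 18347 CPM (adjusted p = 0.289), and it passed with voom, without wild-type-labelled replicate 1 or 3 and with replicate 1 of both groups left out. Another, at 148107439 to 148107916, was at 9908 ± 2064 against 3150 ± 3471 CPM, with a log2 fold change of 1.66 that was 2.89 without wild-type-labelled replicate 2 and 1.03 without replicate 3 of that group, and that from Mapkap1 at 9054 ± 3931 against 5398 ± 1246 CPM. The circRNA from Smim14 had 0 counts in each knockout-labelled library and 12, 22 and 31 in the others (adjusted p = 0.275). That from Sult1c3, a sulfotransferase gene, had 0, 0 and 10 counts against 23, 33 and 68 (adjusted p = 0.99). The circRNA from Lrp6, which encodes a Wnt co-receptor, was at 7138 ± 1672 against 12153 ± 2521 CPM. Those from Man2a1 and Itfg1 had 2 counts each in the knockout-labelled libraries and 34 and 37 in the others, ratios of 17.6 with a counting interval of 4.52 to 152 and of 19.2 with one of 4.95 to 164. Each of the circRNAs from Sult1c3, Man2a1 and Itfg1 had its knockout-labelled counts in 1 library (replicate 3, 2 and 3). Without it the log2 fold changes went from -3.57 to -8.32, from -3.83 to -6.60 and from -3.81 to -6.44. With no knockout-labelled counts left, the size of these values is a model fit, not a measured fold. The value was -2.90 for Sult1c3 without knockout-labelled replicate 1 and -3.09 for Itfg1 without wild-type-labelled replicate 3. The abundant circRNAs from Spidr, Nfix and Btaf1 were at 27889 ± 3744 against 34292 ± 13063, 28918 ± 2519 against 26937 ± 5977 and 21021 ± 3740 against 21432 ± 8894 CPM, each with an adjusted p of 0.99.

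No list fixed beforehand had the 5 tested circRNAs that a set test needed, and no tested member of one passed, either over all circRNAs or adjusted over the list alone. Of the widely reported circRNA hosts, circRNAs from Ubn2, Homer1 and Hipk3 were tested, at 6569 ± 445 against 3567 ± 3091, 7207 ± 2362 against 5181 ± 4639 and 2062 ± 1893 against 2201 ± 1164 CPM. For Sertoli cells, that from Tf was at 3680 ± 2705 against 1615 ± 325 CPM, and for Leydig cells that from Srd5a1 was at 1644 ± 1684 against 764 ± 1324 CPM. The log2 fold change for Srd5a1, 1.12, was 6.14 without wild-type-labelled replicate 1, which held all 8 counts of its group, and 0.11 without knockout-labelled replicate 2. That for Tf went from 1.17 to 0.448 without knockout-labelled replicate 2, and that for Ubn2 from 0.874 to 0.228 without wild-type-labelled replicate 2. The 6.14 for Srd5a1 is a model fit with no wild-type-labelled counts left, so its size is not a measured fold. The directions for circRNAs from Nfix, Btaf1, Homer1 and Hipk3 changed under some alternatives.

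Circular RNA as a whole did not differ detectably. The knockout-labelled libraries held 308.7 ± 59.4 circRNAs with at least 2 counts and the wild-type-labelled ones 446.7 ± 121 (SD, n = 3, two-sided exact permutation p = 0.3). Per 1000 ncRNA counts there were 0.964 ± 0.0388 and 1.13 ± 0.359 circRNA counts (n = 3, exact permutation p = 0.8), and without wild-type-labelled replicate 3 the difference changed sign. With 3 against 3 libraries the smallest p this test can give is 0.1.

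Hosts known from testis cell types held few circRNA counts in any of the libraries. The meiosis and the spermatid lists had 0 of 30106 counts, which allows a share of up to 0.0123% (upper end of the 95% exact binomial interval). The spermatogonia list had 11 counts, all from Zbtb16. Sertoli cell hosts held 0.399% of the counts (95% exact binomial interval 0.331 to 0.476), 105 of 120 counts from Tf, which hepatocytes also express. Leydig cell hosts held 0.103%, all from Srd5a1, and peritubular and matrix hosts 0.0432%, all from Fn1. Leukocyte hosts held 0.0864% and endothelial ones 0.0664%. Heme, iron and antioxidant hosts held 0.126%, the hosts of c-Jun, TOX and cell death 0.329% and the widely reported circRNA hosts 1.61%. The lncRNA list held 5 counts, from Gas5, and the structural small ncRNAs 0. Between the labelled groups, the exact permutation p of these shares was 0.4 for Sertoli cells, 0.7 for Leydig cells, 0.8 for leukocytes, 0.4 for endothelial cells, 0.5 for the heme list, 1 for the c-Jun list and 0.3 for widely reported hosts.

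By contrast, Cyp2c7 alone gave 15.2% of all circRNA counts. A list of 84 genes typical of hepatocytes, written after the tables had been seen, held 22.2% of the counts, through 31 hosts and 77 circRNAs. Its share was 28.3% ± 0.637 in the knockout-labelled libraries and 16.2% ± 2.04 in the wild-type-labelled ones (SD, n = 3), from 13.8% in the lowest library to 28.7% in the highest. That difference came from hosts known to differ by sex in rat liver, chiefly Cyp2c7, since the other 27 hosts held 5.62% ± 0.267 and 5.55% ± 1.78 (SD, n = 3). Other hosts on it included Cps1, the carbamoyl phosphate synthetase of the urea cycle, with 1.01% of all circRNA counts, and Alb, which encodes serum albumin, with 0.634%. Lists for kidney tubule and neuron held 0 counts and one for heart and skeletal muscle held 15.

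**Figure D3:**
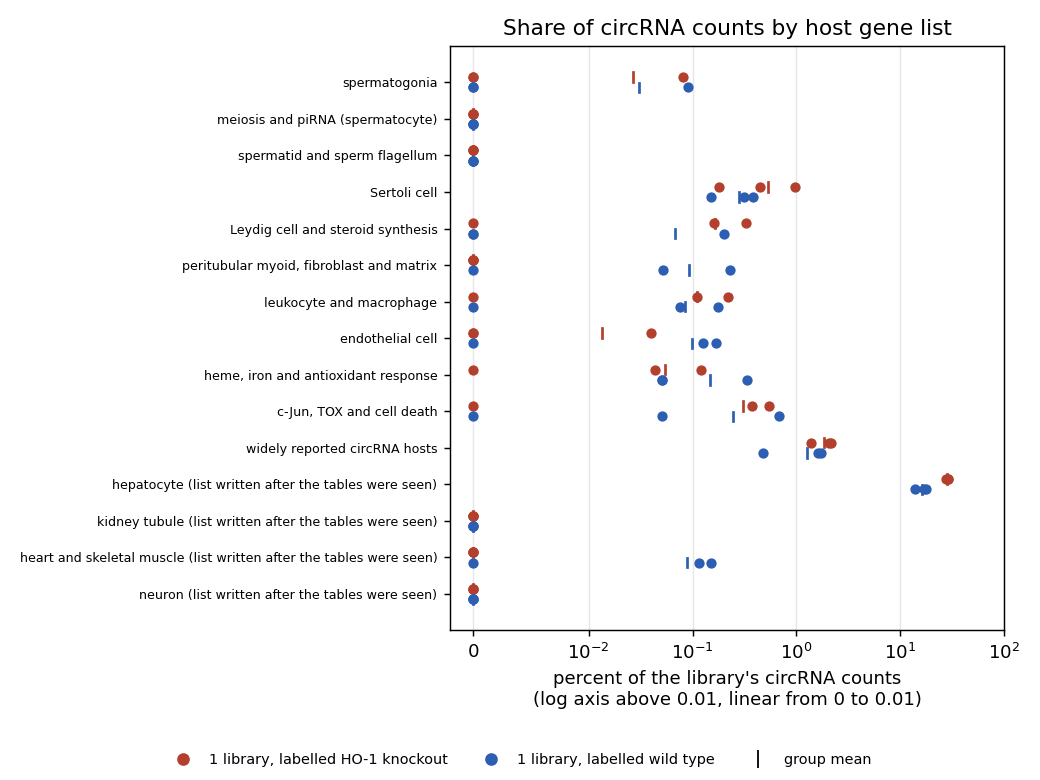
Share of each library's circRNA counts, in percent, from hosts of each gene list, on a log axis that is linear from 0 to 0.01, with a point per library and a bar at each group's mean. The hepatocyte list lies between 13.8% and 28.7% in all 6 libraries, and the meiosis and spermatid lists lie at 0.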

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

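The library sizes from the authors' RPM, the test without Rn7sl1 and the row named Rmrp, and the test without replicate 1 of both groups were chosen after seeing the data. The ncRNA count of 71 lay between 49 and 104 under other scalings, tools, filters and left-out libraries, and all 71, or the 61 of them that the stricter filter tested, had the same direction in each. The unadjusted threshold gave 197, with 92 higher and 105 lower, by construction more. With 1 library left out the count was 49 to 72, with 21 to 35 higher, the lowest without knockout-labelled replicate 3. The circRNA count of 2 was then 0 to 4, with 0 to 3 higher and 0 to 1 lower: 0 without knockout-labelled replicate 2 or 3, 1 without knockout-labelled replicate 1 and 4 without wild-type-labelled replicate 1. It was 0 with DESeq2, with library sizes from the ncRNA table and with those from the authors' RPM, and 1 with counts summed per host gene. With no filter 1 was higher and 1 lower, without replicate 1 of both groups 1 was lower, and the unadjusted threshold gave 1 higher and 2 lower. Replicate numbers showed no sign of pairing the samples. Same-number deviations correlated at -0.00153, -0.0104 and -0.013 for ncRNAs and at -0.0697, -0.0655 and -0.0173 for circRNAs. No library correlated best with its own number, for ncRNAs or for circRNAs. With 3 libraries a group this cannot exclude pairing. The replicate block called 76 ncRNAs, 69 of them among the 71, and 1 circRNA, since that from Cyp2c12 no longer passed, while LOC680406 did. Over the single features and lists, 881 values kept direction and side of the threshold, 24 lost a call, 13 gained one and 27 turned direction. The cause was not tested for any of these.

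Those that turned had not passed. The log2 fold change of H19 became 0.00407 with voom and 0.39 without replicate 1 of both groups, where that of Fancm became 0.0206 and of circHipk3 0.545. With library sizes from the RPM, circHipk3 was at 0.0135. For circBtaf1 it was 0.0676 by library totals, 0.071 with voom and 0.0468 with the replicate block. With 1 library left out it ranged from -0.179 to 0.269 for Rn7sl1, -0.801 to 0.466 for H19, -0.0711 to 0.334 for circNfix, -0.281 to 0.242 for circBtaf1, -0.173 to 1.08 for circHomer1 and -0.818 to 0.563 for circHipk3. By fry, 1 ncRNA list passed, the well characterised lncRNAs (adjusted p = 0.0271), a test that does not compare them with other genes. The class misc_RNA turned with fry (adjusted p = 0.879), and it and lincRNA with the replicate block (adjusted p = 0.985 for each). With 1 library left out the adjusted p was 0.774 to 0.935 for lincRNA, 0.333 to 0.935 for misc_RNA and 0.254 to 0.986 for the class ncRNA. The difference in circRNA counts per 1000 ncRNA counts was then -0.282 to 0.0428, and that in the percentage of circRNA counts was -0.0292 to 0.0811 for leukocyte, -0.139 to 0.00425 for heme and iron, and -0.0634 to 0.28 for c-Jun, TOX and cell death hosts.

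The spread between libraries limits the circRNA calls. On simulated counts of the same depth, 0.1 times the dispersion raised the recovery of log2 changes of 3 from 21% to 89.7%. For log2 changes of 1 it went from 0.774% to 13.9%. Depth and the number of libraries were not varied, so their part in the missed calls is not known. Depth limits which features could be tested, 167 of 1284 circRNAs. No fixed host list reached 5 tested circRNAs, so its other alternatives were not run. With no filter 4 lists could be tested, and the lowest adjusted p was 0.527, for Sertoli cells. Pseudocount alternatives were not run, because both tables hold counts.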

Other observations

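The precursors, the shares of sex-dependent hosts, and the tests of liver RNA, germ-cell loss, HO-1 loss, read number, the knockout label and background reads were chosen only after the result was seen. The miRNA precursor Mir3591, which lies on the strand opposite the liver miRNA Mir122, had 172, 262 and 301 counts in the knockout-labelled libraries and 270, 414 and 226 in the others (adjusted p = 0.727), and with no strand setting given, reads from these precursors cannot be assigned to a strand. Mir22 was at 29.4 ± 1.55 against 86.5 ± 52.3 CPM (edgeR adjusted p = 0.0806), and Mir802 had 141 counts against 130.

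The changed counts were set against all 10 splits of the 6 libraries into 3 and 3. The labelled split was the 1 split with as many as 71 ncRNAs, and the highest other split called 0. It was also the 1 split with 2 circRNAs, where the highest other called 0. Such splits are too few for a share under 0.05.

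The circRNA hosts in libraries labelled testicle included many typical of liver. Leaving out sex-dependent genes such as Cyp2c7, which had first drawn attention, 27 hosts of the hepatocyte list still held 3.59% of circRNA counts in the lowest library and 7.06% in the highest, and 2 of its 84 genes (Tf and Hsd11b1) are also on testis lists. A candidate explanation is that the libraries were made from liver rather than testis. A minority of liver RNA mixed into testis RNA stays open. Germ-cell hosts held at most 0.0907% of a library's counts. Loss of germ cells after torsion predicted a larger share for Sertoli, Leydig and peritubular hosts than for hepatocyte hosts. Instead the 27 hepatocyte hosts held at least 4.54 times the share of these somatic hosts in each library, against that prediction. Tf counts on both sides of that ratio. It gave all 44 Sertoli counts of knockout-labelled replicate 2, where the shares were 5.89% and 1.3%. How many circRNAs rat testis makes from germ-cell or these somatic hosts is not known from these data. These shares therefore do not exclude germ-cell loss.

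For Xist, the lowest knockout-labelled library had 160 times the CPM of the highest wild-type-labelled one. A candidate explanation is that the knockout-labelled animals were female and the wild-type-labelled animals male, against the labels. The 1 ncRNA that the gene table places on the Y chromosome, LOC103694537, had 0 counts in each knockout-labelled library and 4, 2 and 10 in the others, a difference of 16 counts. At least 5 in each wild-type-labelled library had been set as the bound before these counts were seen, so they are too few and the explanation stays open. Sex-dependent circRNA hosts of rat liver do not decide it, because most had been seen before their list was written. Female-predominant hosts held 22.7% ± 0.884 against 9.87% ± 2.17 of circRNA counts (SD, n = 3), and male-predominant ones had 10 counts against 228. Loss of HO-1 in animals of one sex cannot be told apart from it, since 0 rows measure Hmox1 and genotype and Xist follow the same labels.

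The excess of ncRNAs in knockout-labelled replicate 1 was not explained by a larger number of reads in that library, because after thinning all libraries to 4171371 counts it still had 938 more than the next. The knockout label would raise the other libraries of that group too, but the higher of them was lower than the lowest wild-type-labelled library (a difference of -151). Background reads from genomic DNA or unspliced RNA may be the source, and this cannot be told apart here, since 36.9% of the transcripts particular to that library have an entry with a length in the gene table and the check needs 80%.

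A circRNA from the Y-linked Ddx3 had 4 counts in wild-type-labelled replicate 2 and none elsewhere, too few to compare. Cyp2c11 had 14 circRNA counts and Ust5r 4, all in wild-type-labelled libraries.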
